A study of Mus musculus with 33 samples.

How the data were processed

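The values used were counts of gRNAs per library, as deposited by the authors, with a table per reporter line. Per the labels, gRNAs were introduced into mouse embryonic stem cells that carried a placeholder guide at the ROSA26 locus, genomic DNA was taken from unsorted (bulk), GFP-medium and GFP-negative populations, and libraries were made by PCR. Positions refer to mm10, per the submitters' processing notes. The program that turned reads into gRNA counts, its settings and the number of sorted cells are not given in the sources used here. No molecular identifiers are mentioned in the labels. The files hold whole numbers with a different total in each library and were taken as raw counts without normalization. Groups and replicate numbers came from the sample titles, except for the GFP-negative library of Rpp25, whose title names Rpp26; its description and tagged-gene field name Rpp25 and were followed. Of 33 samples 27 were screen libraries. The other 6, deep sequencing of single target sites, had no measurement in the tables used here and were not analysed here.

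Each table listed 3908 gRNAs with an interval, 10 GFP-targeting gRNAs and the placeholder guide. The GFP-targeting gRNAs carry no name of their own and are numbered 1 to 10 here in the order of the table. The placeholder is no library gRNA and was left out of totals and tests. Its share of all counts was 3.53% to 11.3% in Tdgf1 bulk, 0.0198% to 0.178% in Tdgf1 GFP-medium and 0.104% to 0.370% in Tdgf1 GFP-negative libraries, 1.09% to 23.5%, 0.0212% to 4.27% and 0.000352% to 0.596% in those of Zfp42, 0.633% to 0.663% in bulk and 0.0357% to 0.0386% in GFP-negative libraries of Nanog, and 0.609% and 0.000300% in the Rpp25 libraries. In bulk of the Zfp42 line it was 1.22% and 1.09% in replicates 1 and 2 and 22.5% and 23.5% in replicates 3 and 4, which parted the replicates into 2 batches, so within-batch values were computed. Positions listed more than once (1 in Tdgf1, 4 in Zfp42) were kept apart.

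Intervals are given as deposited. Whether they count from 0 or 1 is not given in the sources used here: all 6 sites listed for the deep sequencing match a gRNA that starts 1 bp lower in the count tables, and 1 also matches a gRNA at the listed start. The libraries span chr9:110926151-110966228 (Tdgf1), chr8:43180015-43365026 (Zfp42), chr6:30173553-122771575 (Nanog) and chr9:57462121-65197097 (Rpp25), in several clusters for the last 3.

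Genes were taken from a table of RefSeq genes of the matching assembly that gives gene spans without exons or strands. The strands of the 4 tagged genes were added from general knowledge. Planned classes that need exons and introns were therefore merged, and gRNAs were sorted in this order: GFP-targeting; own promoter, within 2 kb of the annotated 5' end of the tagged gene; within 1 kb of either end of another protein-coding gene; body of the tagged gene; body of another gene; intergenic. Without strands, the planned promoter class of other protein-coding genes became the class within 1 kb of either gene end. Because only 1 span per gene was used, alternative start sites were not considered. For the short Rpp25 gene the own-promoter class covers the gene body.

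Each replicated line was fitted alone with edgeR 4.0.16 in R 4.3.3. The gRNAs were kept by filterByExpr with its minimum count of 10, scaled by TMM, and tested with the robust quasi-likelihood F test (2-sided), with all populations of the line in the fit and Benjamini-Hochberg adjustment at 0.05. This left 3172 gRNAs in Tdgf1, 1342 in Zfp42 and 1232 in Nanog. Classes and 1-kb tiles with at least 5 tested gRNAs were compared with the other tested gRNAs by camera of limma 3.58.1, with the preset correlation of 0.01 and, as a check, with the correlation estimated from the data. Adjusted p-values of classes and tiles are from camera, those of single gRNAs from edgeR unless DESeq2 1.42.0 or limma-voom is named. Class shares were also compared by 2-sided exact permutation tests, which ignore the replicate numbers; swapping populations only within a number, a test chosen after the data were seen, cannot go below p = 0.25 with the 3 pairs of Tdgf1 or 0.125 with the 4 pairs of Zfp42. Numbers of gRNAs whose libraries separate completely are set against the share that exchangeable libraries would give, an upper limit since ties lower it. For a gRNA without counts in any library of a population the fold is a lower bound, computed with 3 counts per library. This bound uses the mean of the other population and leaves out the spread between replicates. The Rpp25 line had no replicates: log2 ratios of CPM were taken after adding 1 CPM, shares have exact Clopper-Pearson 95% intervals, and class medians were set against 10000 random sets of gRNAs matched on bulk abundance. Plots were drawn with matplotlib 3.10.9 in python 3.11.15.

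The groups, tests, classes, alternatives and the rule for named gRNAs were set before the data were examined. The classes used differ from those set by the changes given above. The rule names, in each replicated comparison, the GFP-targeting gRNAs, the 10 largest increases past the adjusted threshold that separate the libraries completely, the 5 such gRNAs more than 2 kb from the 5' end, the 3 largest decreases past the threshold and the 5 tiles with the smallest adjusted p, and in Rpp25 the 10 largest ratios among gRNAs with at least 50 bulk counts. Since few positioned gRNAs passed, a further rule was chosen after seeing the data: the 5 promoter gRNAs and the 5 gRNAs beyond 2 kb with the widest gap between populations among those whose libraries separate completely. Only part of the gRNAs these rules give are described.

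Alternatives set at the same stage were other scalings (DESeq2's size factors, TMMwsp, total counts), other filters (none, or a bulk mean of at least 10), DESeq2's Wald test, limma-voom with quality weights, only the populations compared in the fit, the replicate number as a block, each library left out in turn, promoter windows of 1 and 5 kb, tiles of 500 bp and 2 kb, and for Rpp25 pseudocounts of 0.1 and 10 CPM. Counts of gRNAs whose libraries separate completely, fits within replicates 1 and 2 and within replicates 3 and 4 of Zfp42, classes without their 3 most counted gRNAs and shares without GFP-targeting counts were added after seeing the data.

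Same-numbered samples of a line deviated together from the means of their populations: the correlations of these deviations were 0.147 to 0.487 in Tdgf1 and 0.105 to 0.270 in Zfp42, and every sample correlated best with its own number. By this check the numbers pair the samples in both lines. In Nanog, with 2 pairs, the check has a fixed outcome and was not used.

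No library repeated another: the chi-square per degree of freedom between replicates was 5.61 to 18.2 in bulk and 224 to 928 in sorted populations, where sampling alone gives about 1. Spearman correlations between replicates over all gRNAs were 0.600 to 0.681 in Tdgf1 bulk, 0.933 to 0.937 in Zfp42 bulk and 0.923 in Nanog bulk, and 0.228 to 0.337, 0.401 to 0.462 and 0.504 in the GFP-negative libraries of these lines. Total counts were 39096 to 123840 in bulk and 121455 to 719247 in sorted libraries, and edgeR's common dispersion was 3.86 in Tdgf1, 3.63 in Zfp42 and 1.79 in Nanog, so a single gRNA is measured with a large error. The procedure was tested on simulated counts with 100 gRNAs raised and 100 lowered 16-fold in GFP-negative libraries. At the dispersion of the libraries it called 0 of the raised and 0 of the lowered gRNAs in each of the 3 lines (2977, 1283 and 1156 gRNAs in the step), and at a dispersion of 0.1 it called all 100 of each with 10, 8 and 4 false calls (3169, 1342 and 1229 gRNAs). A tile raised 16-fold at the dispersion of the libraries was called in all 3 lines (adjusted p = 3.63e-14 in Tdgf1, 3.29e-07 in Zfp42 and 5.03e-13 in Nanog), with 0, 1 and 0 other tiles called. This tile check did not filter the simulated counts and set no minimum number of gRNAs per tile. It used the preset correlation only and drew the gRNAs independently, so it does not test the tile calls under correlated gRNAs. The simulation drew bulk and sorted libraries with the same dispersion, although real bulk replicates lay closer together. It therefore does not measure power in the real comparisons.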

Results

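The series is a CRISPR mutation screen in mouse embryonic stem cells, the pluripotent cells of the early embryo kept in culture. In each of 4 reporter lines a GFP sequence had been placed at 1 gene: Tdgf1 (a membrane co-receptor for Nodal signals, also called Cripto), Zfp42 (a zinc finger protein also called Rex1), Nanog (a homeobox transcription factor of pluripotent cells) or Rpp25 (a protein subunit of ribonuclease P). GFP replaced sequence at the transcription start site of Tdgf1 and Zfp42 and was fused to the C-terminus of Nanog and Rpp25. A placeholder guide at the ROSA26 locus was exchanged for a library guide RNA (gRNA). The gRNAs were then counted from genomic DNA of the unsorted bulk population and of cells sorted as GFP-negative or, for Tdgf1 and Zfp42, GFP-medium. The screen asks at which positions around a gene mutations are over-represented among cells that lost part or all of their GFP signal. The GFP-targeting gRNAs are the positive controls.

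There were 27 screen libraries. The Tdgf1 line had 3 replicates of each of 3 populations, the Zfp42 line had 4 replicates of each of 3 populations, the Nanog line had 2 replicates of bulk and of GFP-negative cells, and the Rpp25 line had 1 library of each of those 2 populations and no replicates. Each line carried its own library of 3908 gRNAs with a genomic position plus 10 GFP-targeting gRNAs. Total gRNA counts per library were 107960 to 123840 in bulk, 379072 to 461825 in GFP-medium and 608532 to 719247 in GFP-negative cells of the Tdgf1 line. In the Zfp42 line they were 39096 to 82959, 121455 to 268197 and 252023 to 487732. Nanog libraries held 62654 to 69662 counts in bulk and 142821 to 196665 in GFP-negative cells, and the Rpp25 libraries held 74318 and 333608. Sorted libraries held more counts than bulk libraries of the same line, but fewer different gRNAs. A bulk Tdgf1 library detected 3455 to 3635 gRNAs and a GFP-negative one 992 to 2106; the ranges were 1598 to 1689 and 335 to 540 for Zfp42, 1612 to 1619 and 817 to 820 for Nanog, and 1807 and 362 for Rpp25. The 10 most counted gRNAs took 1.30% to 1.68% of a Tdgf1 bulk library and 9.90% to 13.5% of a GFP-negative one, and 50.6% of the Rpp25 GFP-negative library. In the Zfp42, Nanog and Rpp25 lines 2200, 2244 and 2111 gRNAs had no count in any library, against 141 in the Tdgf1 line. Nothing in the labels says that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

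Values below are shares of all gRNA counts of a library (mean ± SD over the replicates of a population) or CPM, a gRNA's count scaled by the total of its library. A share cannot tell more copies of some gRNAs from fewer copies of the others, so a rise or fall is relative to the rest of the library. The scaling used in the fits moves the median log2 change of all tested gRNAs by between 0.49 and 2.75, depending on the comparison. Group tests compare a class or a 1-kb tile with the other tested gRNAs of the line and are relative to that median.

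In the Tdgf1 line, gRNAs near the 5' end of Tdgf1 and GFP-targeting gRNAs took larger shares of GFP-negative than of bulk counts. The 457 gRNAs within 2 kb of the Tdgf1 5' end took 13.1% ± 0.288 of bulk counts and 35.9% ± 5.48 of GFP-negative counts (n = 3 each), a log2 ratio of 1.46. Singly, of 421 tested gRNAs of this class edgeR called 0 enriched and 19 depleted (0 and 29 at an unadjusted p under 0.05), DESeq2 28 and 25, and limma-voom 13 and 83. GFP-targeting gRNAs went from 0.210% ± 0.0289 to 6.52% ± 1.94, a log2 ratio of 4.96. Opposite to these, gRNAs in the body of the neighbouring gene Lrrc2, which encodes a leucine-rich repeat protein, fell from 33.6% ± 0.149 to 20.0% ± 2.24, and intergenic gRNAs fell from 35.4% ± 0.390 to 24.1% ± 2.34. The gRNAs in the rest of the Tdgf1 body (12.0% in bulk, 7.71% ± 1.62 in GFP-negative) and at the end of Lrrc2 (5.76% in both) did not pass the test. By camera, the adjusted p was 9.99e-24 for the own-promoter class (0.0237 with an estimated correlation) and 1.74e-15 for GFP-targeting gRNAs (0.00424 with an estimated correlation). For Lrrc2 and intergenic gRNAs it was 0.00352 and 0.00854, but adjusted p = 0.474 for both with an estimated correlation, and the intergenic call also ended when the promoter class was narrowed to 1 kb (adjusted p = 0.380). An exact permutation test of 3 against 3 libraries cannot go below p = 0.1, which is the value it gave for both enriched classes (adjusted p = 0.12 over 6 classes).

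By position, the enrichment over bulk formed a single block around the Tdgf1 5' end at chr9:110946158 (mm10). Of 41 tiles tested, 6 neighbouring tiles from 110944000 to 110949999 were higher and 5 tiles farther away were lower. The tile at 110946000 to 110946999, which holds the 5' end, went from 4.08% ± 0.0669 to 16.6% ± 1.49 of counts (log2 ratio 2.03, adjusted p = 6.97e-19), and the next tile upstream, starting at 110947000, went from 3.66% ± 0.262 to 11.4% ± 4.51 (1.63, adjusted p = 6.75e-16). The tile starting at 110945000, inside the gene, went from 2.17% ± 0.0421 to 3.72% ± 0.390 (0.78, adjusted p = 1.21e-05). Smaller differences were called at 110948000 (0.73, adjusted p = 0.0135), 110949000 (0.26, adjusted p = 0.0135) and 110944000 (0.14, adjusted p = 0.0492). With an estimated correlation 0 tiles passed by camera (adjusted p = 0.201 for the leading 2), and without GFP-negative replicate 2 the number of higher tiles was 3.

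**Figure D1:**
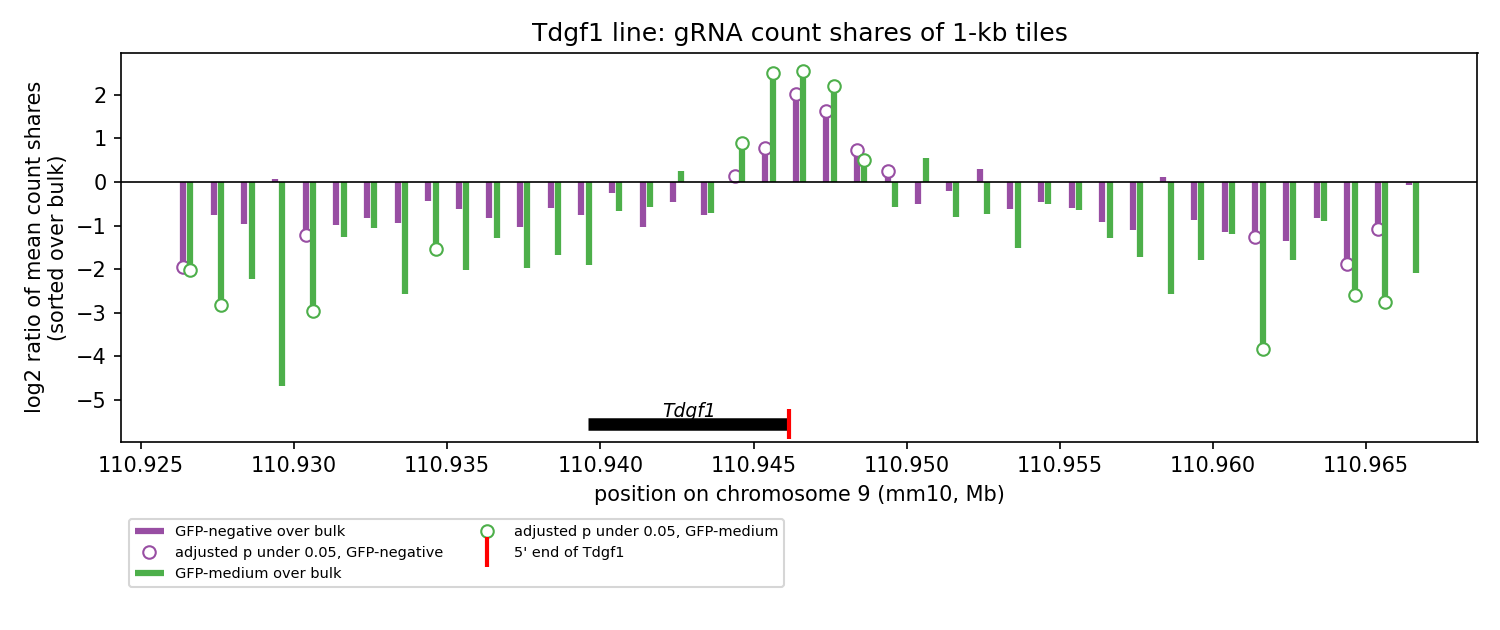
Log2 ratio of mean count shares (sorted over bulk) for 1-kb tiles along chromosome 9 (mm10, Mb) in the Tdgf1 line, with GFP-negative in purple, GFP-medium in green, open circles at tiles with an adjusted p under 0.05 by camera, a black bar over Tdgf1 and a red mark at its 5' end. The highest bars stand at the 5' end, where the tile starting at 110946000 has a log2 ratio of 2.03 in GFP-negative and 2.56 in GFP-medium cells.

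Single gRNAs were measured with far less precision. In edgeR's test 0 of 3172 tested gRNAs were enriched in Tdgf1 GFP-negative cells and 705 were depleted, while at an unadjusted p under 0.05 there were 5 higher and 886 lower. DESeq2 called 40 enriched and 854 depleted, limma-voom called 22 and 1739. In all 3 GFP-negative libraries 59 gRNAs (1.51%) lay above all 3 bulk libraries and 1646 (42.0%) lay below, where exchangeable libraries give at most 5% in each direction. Over all gRNAs, fewer than this limit lay above in every replicated comparison. Ties at 0 lower this limit, so the comparison cannot tell whether more gRNAs lay above than chance gives. Lying above bulk in every library was therefore not taken by itself as evidence for a gRNA picked from the whole library. Here 90% of GFP-targeting and 8.97% of own-promoter gRNAs lay above, and at most 0.458% of any other class. Of the 705 depleted gRNAs 639 (90.6%) had no count in any GFP-negative library. All 10 GFP-targeting gRNAs had a higher mean in GFP-negative cells, with log2 changes from 2.83 for gRNA 7 to 5.64 for gRNA 9 (8196 ± 1466 against 192 ± 167 CPM, adjusted p = 0.0993). None passed edgeR's test, over all gRNAs or adjusted over the list alone, whereas DESeq2 called 9 and 9 lay above bulk in every library. Among promoter gRNAs that lay above bulk in every library, a group chosen after the data were seen, chr9:110946710-110946732 (at −563 bp from the 5' end) had 4384 ± 1028 CPM in GFP-negative and 442 ± 110.1 CPM in bulk (edgeR adjusted p = 0.511, DESeq2 adjusted p = 0.0217). chr9:110947349-110947371 (at −1202 bp) had 3065 ± 2146 against 305 ± 47.3 CPM (0.265 and 4.32e-04). Beyond 2 kb, chr9:110948259-110948281 had 2512 ± 1012 against 406 ± 184 CPM, and chr9:110939616-110939637 in the 3' part of Tdgf1 had 1723 ± 1554 against 269 ± 49.1 CPM; neither passed edgeR or DESeq2. The 3 largest decreases past edgeR's test had no count in GFP-negative cells: chr9:110936814-110936836, intergenic, with 1491 ± 214 CPM in bulk was at least 319.7-fold lower (adjusted p = 0.0329), chr9:110937036-110937058 at least 218-fold lower (0.0377), and chr9:110965049-110965071 in Lrrc2 at least 190.2-fold lower (0.0400).

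The number of depleted gRNAs in the Tdgf1 GFP-negative comparison depended on how the libraries were modelled. With the replicate number as a block it was 0. It was 462 without bulk replicate 1, 462 without bulk replicate 2 and 1341 without GFP-negative replicate 2. The number enriched was 3, 2 and 5 without GFP-medium replicate 1, 2 or 3, and 1 without GFP-negative replicate 1 or 2.

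In GFP-medium cells of the Tdgf1 line the promoter gRNAs made up most of the counts, and GFP-targeting gRNAs did not. The own-promoter class took 60.8% ± 7.38 of GFP-medium counts against 13.1% ± 0.288 in bulk (n = 3 each, log2 ratio 2.22). Singly, edgeR called 0 of its 421 tested gRNAs enriched and 50 depleted (7 and 67 at an unadjusted p under 0.05), DESeq2 71 and 47, and limma-voom 22 and 127. GFP-targeting gRNAs took 0.20% ± 0.189 against 0.210% ± 0.0289 (log2 ratio −0.07). Lrrc2 body gRNAs fell to 12.0% ± 4.49 and intergenic gRNAs to 13.8% ± 3.14. The gRNAs in the rest of the Tdgf1 body took 9.06% ± 1.55 and those at the end of Lrrc2 4.08%, and neither passed. The own-promoter class had adjusted p = 5.03e-32 by camera (0.0250 with an estimated correlation). Lrrc2 and intergenic gRNAs had 0.00236 and 0.00298, with adjusted p = 0.475 for both with an estimated correlation, and the intergenic call ended with the promoter class at 1 kb (adjusted p = 0.367). GFP-targeting gRNAs had adjusted p = 0.0674. Here the direction was not settled: the median fitted change of these gRNAs was −1.40 with TMM (−1.60 at the floor), −0.52 with TMMwsp, −1.64 with total counts and 0.16 with DESeq2's size factors, and camera ranked them above the other gRNAs, whose median was −6.44. Without GFP-medium replicate 3 their log2 share ratio was 0.42 with adjusted p = 0.00832. Without GFP-negative replicate 1, 2 or 3 the adjusted p was 0.0209, 0.0151 or 0.0154. Leaving these out keeps the compared libraries but refits the filter, the scaling and the shared spread.

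The tiles with most GFP-medium counts again lay at the Tdgf1 5' end. The tile starting at 110946000 took 24.0% ± 2.01 (log2 ratio 2.56, adjusted p = 2.49e-22), that at 110947000 took 17.0% ± 7.19 (2.21, adjusted p = 2.49e-22) and that at 110945000 took 12.3% ± 0.897 (2.50, adjusted p = 6.28e-10). In addition 110944000 went to 5.92% ± 1.10 (0.90, adjusted p = 0.0133) and 110948000 to 3.83% ± 0.551 (0.51, adjusted p = 0.0447). In all 5 tiles were higher and 7 lower of 41, and 0 of either with an estimated correlation by camera (adjusted p = 0.140 for the leading 2).

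EdgeR called 0 gRNAs enriched and 1278 depleted in Tdgf1 GFP-medium cells (7 higher and 1575 lower at an unadjusted p under 0.05), DESeq2 called 83 and 1321, and limma-voom 24 and 2176. Complete separation of the libraries was seen for 29 gRNAs (0.740%) above bulk and 2284 (58.3%) below, where exchangeable libraries give at most 5% in each direction. Of the depleted gRNAs 1222 (95.6%) had no count in GFP-medium cells. The highest promoter gRNAs among those above bulk in every library, chosen after the data were seen, included chr9:110945839-110945861 (at 308 bp inside the gene) with 6393 ± 1408 against 248 ± 129 CPM (edgeR adjusted p = 0.0846, DESeq2 5.88e-05). Upstream, chr9:110947436-110947458 had 9513 ± 8747 against 420.4 ± 169.5 CPM (0.0802 and 8.62e-06) and chr9:110947522-110947544 had 6323 ± 1776 against 567 ± 115 CPM (0.133 and 6.47e-05). The largest decreases past edgeR's test were chr9:110936814-110936836 (at least 212-fold lower, adjusted p = 0.0296), chr9:110944136-110944158 at the inner edge of the promoter class (at least 158-fold, 0.0306) and chr9:110940081-110940103 in the Tdgf1 body (at least 151-fold, 0.0324). The depleted number was 681, 804 or 733 without bulk replicate 1, 2 or 3 and 0 without any of GFP-medium replicates 1, 2 and 3. The enriched number was 6, 6 or 2 without GFP-negative replicate 1, 2 or 3.

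Set directly against each other, GFP-negative and GFP-medium cells of the Tdgf1 line differed in GFP-targeting gRNAs. These took 6.52% ± 1.94 of GFP-negative and 0.20% ± 0.189 of GFP-medium counts (log2 ratio 5.03, n = 3 each, adjusted p = 8.44e-16 by camera, 0.00303 with an estimated correlation). The own-promoter share was 35.9% ± 5.48 in GFP-negative and 60.8% ± 7.38 in GFP-medium cells (log2 ratio −0.76), but the class did not pass (adjusted p = 0.184), its median fitted change was 0.11 with TMM (0.04 with all-zero populations at a floor of 3 counts), 0.04 with total counts, 0.00 with TMMwsp and −0.18 with DESeq2's size factors, so its sign depends on the scaling, and the exact permutation p of the shares was 0.1, the smallest that 3 against 3 allows (adjusted p = 0.12). No class other than the GFP-targeting gRNAs and 0 of 41 tiles passed by camera, but without GFP-medium replicate 1 the tiles starting at 110945000 (log2 ratio −1.75) and 110947000 (−0.89) did, each with adjusted p = 0.0212. EdgeR called 0 single gRNAs in either direction, with 715 higher and 63 lower at an unadjusted p under 0.05, while DESeq2 called 300 and 44 and limma-voom 8 and 0. The libraries separated completely for 83 gRNAs (2.12%) above and 11 (0.281%) below, both fewer than the 5% that exchangeable libraries can give. Adjusted over the list alone, 7 of the 10 GFP-targeting gRNAs were enriched in edgeR's test. The highest was gRNA 4 by counts, with 15867 ± 10238 CPM in GFP-negative and 175 ± 96.2 CPM in GFP-medium cells (log2 6.67, adjusted p = 0.179 over all gRNAs).

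In the Zfp42 line, GFP-targeting gRNAs and gRNAs at the 3' end of Zfp42 took larger shares of GFP-negative than of bulk counts, and those far from the gene took smaller ones. GFP-targeting gRNAs rose from 0.589% ± 0.198 of bulk to 23.4% ± 5.74 of GFP-negative counts (n = 4 each, log2 ratio 5.31). The 652 gRNAs in the Zfp42 body rose from 18.3% ± 0.144 to 33.0% ± 2.52 (0.85). Most of this lay in the 217 body gRNAs of the tiles at 43295000 and 43296000, which went from 6.18% ± 0.519 to 19.7% ± 3.37, while the other 435 went from 12.1% ± 0.590 to 13.3% ± 2.12 (0.13). These are shares of all counts, which GFP-targeting gRNAs lower in GFP-negative cells, and this split was not computed without them. In edgeR's test 0 of 233 tested body gRNAs were enriched and 50 depleted (2 and 53 at an unadjusted p under 0.05), and DESeq2 called 27 and 44 and limma-voom 10 and 109. Intergenic gRNAs fell from 63.4% ± 0.172 to 27.2% ± 3.20 (−1.22) and the 142 gRNAs at Triml1 and Triml2, genes of tripartite motif proteins, fell from 4.56% ± 0.164 to 1.00% ± 1.08 (−2.19). The 453 own-promoter gRNAs took 13.2% ± 0.245 of all bulk counts and 15.5% ± 2.53 of all GFP-negative counts (0.23, exact permutation p = 0.143). Among counts without GFP-targeting gRNAs their GFP-negative share was 20.2% ± 2.94, and the log2 ratio to bulk was 0.61. Camera gave adjusted p = 1.67e-24 for GFP-targeting gRNAs (2.72e-04 with an estimated correlation), 2.97e-11 for the Zfp42 body (0.00135), 7.38e-13 for intergenic gRNAs (0.00585) and 3.54e-04 for Triml1 and Triml2 (adjusted p = 0.0535 with an estimated correlation). The median fitted change of the Zfp42 body was 0.31 with TMM (−0.10 with all-zero populations at the floor), 1.67 with DESeq2's size factors, 2.10 with TMMwsp and −0.15 with total counts, so its sign depends on the scaling while its share was higher in every GFP-negative than in any bulk library. Camera also ranked the own-promoter class above the others (adjusted p = 3.85e-06, 0.0263 with an estimated correlation), although its median fitted change was −0.33 with TMM (−1.01 with all-zero populations at the floor), 0.92 with DESeq2's size factors, 1.47 with TMMwsp and −1.07 with total counts, and the share ratio turned to −0.19 when the class was widened to 5 kb (adjusted p = 0.00648). The share of the placeholder guide in bulk was 1.22% and 1.09% in replicates 1 and 2 and 22.5% and 23.5% in replicates 3 and 4, so both pairs were taken as batches. Within replicates 1 and 2 and within replicates 3 and 4 the log2 ratios were 5.17 and 5.49 for GFP-targeting gRNAs, 0.84 and 0.86 for the Zfp42 body, −1.28 and −1.17 for intergenic gRNAs, −1.31 and −5.06 for Triml1 and Triml2, and 0.14 and 0.32 for the promoter.

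The Zfp42 enrichment in GFP-negative cells was highest at the 3' end of the gene, which spans chr8:43295067-43307009 with its 5' end at 43307009. The tile at 43296000 to 43296999 rose from 3.61% ± 0.294 to 13.8% ± 2.29 (log2 ratio 1.94, adjusted p = 1.02e-15) and its neighbour at 43295000 from 2.65% ± 0.228 to 5.96% ± 1.34 (1.17, adjusted p = 1.00e-08), both with adjusted p = 0.00771 with an estimated correlation. Near the 5' end the tile at 43305000 went from 4.24% ± 0.162 to 6.44% ± 0.424 (0.60, adjusted p = 0.00126) and that at 43306000 from 2.90% to 3.80% ± 0.606 (0.39, adjusted p = 1.29e-04), with adjusted p = 0.167 and 0.118 with an estimated correlation. The other 3 tiles called higher were 43298000 (0.86), 43294000 (0.11, and −0.02 without GFP-negative replicate 2) and 43307000, whose share ratio was −0.00 although camera ranked it higher. In all 7 of 41 tiles were higher and 6 lower, and 2 and 0 with an estimated correlation. The 6 lower tiles lay far from the gene, at Triml1 and Triml2 and at 43330000, 43352000, 43354000, 43355000 and 43364000.

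**Figure D2:**
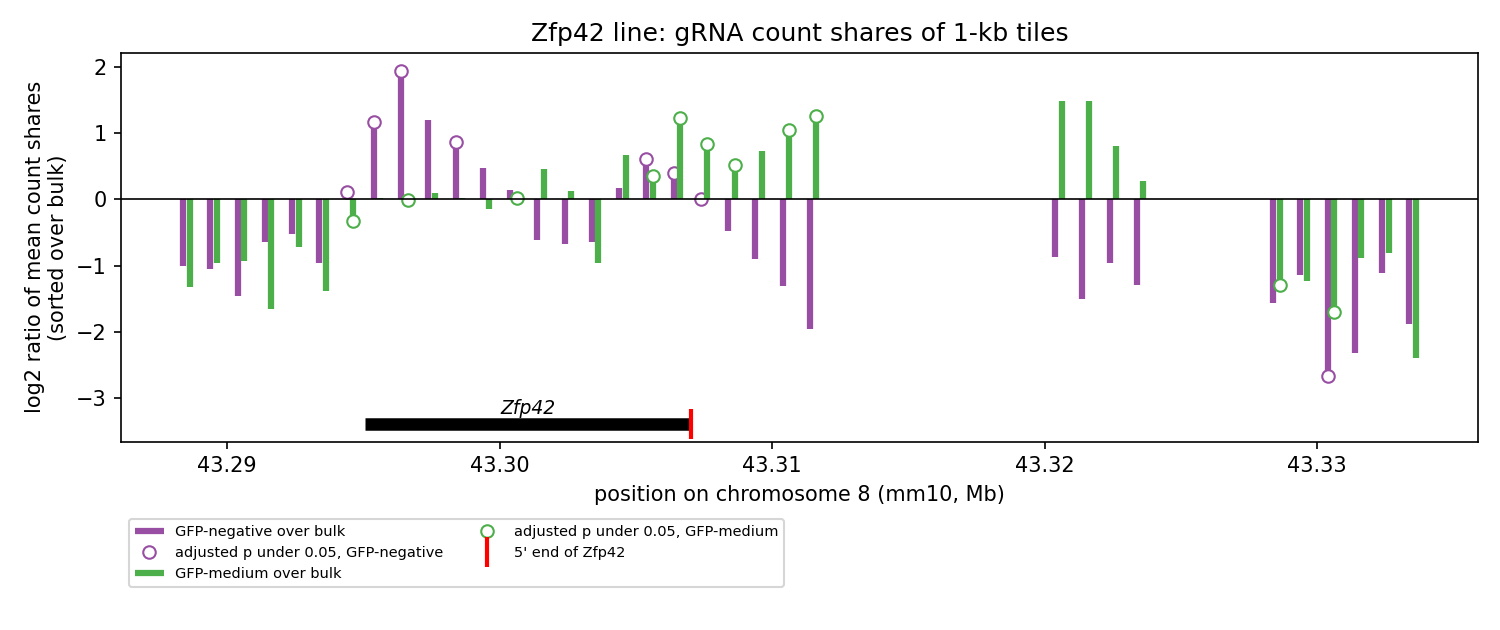
Log2 ratio of mean count shares (sorted over bulk) for 1-kb tiles along chromosome 8 (mm10, Mb) in the Zfp42 line around and to the right of the gene, with GFP-negative in purple, GFP-medium in green, open circles at tiles with an adjusted p under 0.05 by camera, a black bar over Zfp42 and a red mark at its 5' end. The highest GFP-negative bar, 1.94 at 43296000, stands near the 3' end, and GFP-medium bars with a circle reach 1.22 at 43306000 and 1.25 at 43311000.

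EdgeR called 8 of 1342 gRNAs enriched in Zfp42 GFP-negative cells and 598 depleted. All 8 were GFP-targeting, and adjusted over the list alone 9 of the 9 measured GFP-targeting gRNAs passed. The highest was gRNA 3, with 41448 ± 21367 CPM in GFP-negative and 817 ± 269.8 CPM in bulk (log2 6.32, SE 1.85, adjusted p = 0.00571), and gRNA 7 did not pass over all gRNAs (5.59, adjusted p = 0.0778). GFP-targeting gRNA 5 had no count in any Zfp42 or Nanog library. DESeq2 called 58 enriched and 524 depleted, and limma-voom 19 and 1017. The libraries separated completely for 16 gRNAs (0.408%) above and 884 (22.6%) below, where exchangeable libraries give at most 1.43% each. Of those above, chr8:43296492-43296513 in the 3' part of Zfp42, chosen after the data were seen, had 13514 ± 5220 against 1069.7 ± 352 CPM (edgeR adjusted p = 0.0898, DESeq2 1.08e-05). Near the 5' end, chr8:43306951-43306972 had 2421 ± 1900 against 562 ± 205 CPM (0.294 and 4.92e-04). The largest decreases were chr8:43293106-43293127 (2354 ± 734 CPM in bulk, at least 233-fold lower, adjusted p = 0.00635), chr8:43310703-43310724 (at least 228-fold, 0.00547) and chr8:43290403-43290424 (at least 217-fold, 0.00506). Of the depleted gRNAs 451 (75.4%) had no count in GFP-negative cells. The enriched number was 5, 4, 3 or 3 without bulk replicate 1, 2, 3 or 4, and 13 without GFP-medium replicate 1, GFP-negative replicate 1 or GFP-negative replicate 3; it was 0 in replicates 1 and 2 alone and 5 in replicates 3 and 4 alone, against 621 and 426 depleted.

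In GFP-medium cells of the Zfp42 line the promoter gRNAs took a larger share of counts than in bulk, and GFP-targeting gRNAs did not. The own-promoter class rose from 13.2% ± 0.245 to 21.9% ± 1.10 (log2 ratio 0.73, n = 4 each, higher in every GFP-medium library, exact permutation p = 0.0286, the smallest possible, and 0.0714 adjusted over 5 classes, or 0.125 when only same-numbered libraries are swapped, the smallest that 4 pairs allow). Singly, edgeR called 0 of its 169 tested gRNAs enriched and 13 depleted (0 and 24 at an unadjusted p under 0.05), DESeq2 16 and 13, and limma-voom 4 and 44. GFP-targeting gRNAs took 0.589% ± 0.198 of bulk and 0.384% ± 0.391 of GFP-medium counts. The gRNAs at Triml1 and Triml2 fell to 1.74% ± 0.999 (−1.39). Intergenic gRNAs were ranked lower by camera but their share, 57.4% ± 6.44 against 63.4% ± 0.172, differed by less than the spread of the GFP-medium libraries. Camera's adjusted p was 4.33e-08 for the promoter (0.0289 with an estimated correlation), 0.472 for GFP-targeting gRNAs, 2.36e-04 for Triml1 and Triml2 (0.0352) and 7.00e-05 for intergenic gRNAs (0.0440). The Zfp42 body was ranked higher (adjusted p = 0.00425, 0.0462 with an estimated correlation) while its share was 18.6% ± 4.61 against 18.3% ± 0.144, its median fitted change was −0.24 with TMM (−0.89 at the floor), −0.95 with total counts, 0.93 with DESeq2's size factors and 1.06 with TMMwsp, and its log2 share ratio of 0.02 turned to −0.14 without GFP-medium replicate 1 and to −0.23 without its 3 most counted gRNAs. Within replicates 1 and 2 and within replicates 3 and 4 the log2 ratios were 0.79 and 0.68 for the promoter, −1.11 and −0.12 for GFP-targeting gRNAs, 0.26 and −0.26 for the body, −0.26 and −0.03 for intergenic gRNAs, and −0.88 (adjusted p = 0.0510) and −2.21 for Triml1 and Triml2.

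Of the 9 tiles camera called higher in Zfp42 GFP-medium cells, 5 lay at the 5' end of the gene or upstream and 4 farther inside the gene or at its 3' end. The tile at 43306000, which ends beside the 5' end, rose from 2.90% to 6.74% ± 0.623 (log2 ratio 1.22, adjusted p = 3.06e-05) and that at 43307000 from 3.23% to 5.76% ± 2.28 (0.84, adjusted p = 0.00501). Farther upstream the tiles at 43308000 (0.52, adjusted p = 0.00774), 43310000 (1.05, adjusted p = 0.00501) and 43311000 (2.40% ± 0.388 to 5.70% ± 1.84, 1.25, adjusted p = 0.0320) were higher too. Inside the gene 43305000 (0.35, adjusted p = 0.00894) and 43300000 (0.01, adjusted p = 0.0300) were called. At the 3' end the tile at 43296000 held 3.59% ± 0.974, about its bulk share. Of 41 tiles 9 were higher and 7 lower, and 0 of either with an estimated correlation by camera (adjusted p = 0.0781 for 43306000 and 0.156 for 43311000). Among the 9, the share ratio at 43294000 (−0.33) and 43296000 (−0.01) was below 0, so rank and share differ there. EdgeR called 0 gRNAs enriched and 265 depleted (3 and 384 at an unadjusted p under 0.05), DESeq2 33 and 286, limma-voom 9 and 663, and complete separation of the libraries was seen for 10 (0.255%) above and 689 (17.6%) below, where exchangeable libraries give at most 1.43% each. The depleted number was 335 in replicates 1 and 2 alone, 0 in replicates 3 and 4 alone and 482 without GFP-medium replicate 2. The enriched number was 2 without GFP-medium replicate 3 or 4, and 1, 2, 1 or 2 without GFP-negative replicate 1, 2, 3 or 4. Of the gRNAs above bulk in every library, chosen after the data were seen, chr8:43306951-43306972 near the 5' end had 4698 ± 1939 against 562 ± 205 CPM (edgeR adjusted p = 0.214, DESeq2 2.32e-04). The largest decreases were chr8:43291848-43291870 (1830.2 ± 733 CPM in bulk, at least 104-fold lower, adjusted p = 0.0148), chr8:43354740-43354762 (at least 77.0-fold, 0.0138) and chr8:43288647-43288669 (at least 73.2-fold, 0.0132).

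Set directly against each other, the 2 sorted populations of the Zfp42 line differed by position along the locus. GFP-targeting gRNAs took 23.4% ± 5.74 of GFP-negative and 0.384% ± 0.391 of GFP-medium counts (log2 ratio 5.93, n = 4 each), and the Zfp42 body 33.0% ± 2.52 against 18.6% ± 4.61 (0.82), but 13.3% ± 2.12 against 12.4% ± 4.35 outside the tiles at 43295000 and 43296000. The GFP-targeting counts lower every other share of GFP-negative counts, and the body outside these tiles was not computed without them. The 3' tiles at 43296000 (1.95) and 43295000 (1.16) were higher in GFP-negative cells, and upstream tiles at 43311000 (0.621% against 5.70% of counts, −3.20), 43321000 (1.05% against 8.30%, −2.98) and 43310000 (0.606% against 3.10%, −2.35) were higher in GFP-medium cells. Intergenic gRNAs were lower in GFP-negative cells (−1.08), and the own-promoter class, with 15.5% ± 2.53 against 21.9% ± 1.10 (−0.50), did not pass camera (adjusted p = 0.560), although the exact permutation p of its shares was 0.0286, the smallest possible (0.0357 adjusted over 5 classes, and 0.125 when only same-numbered libraries are swapped), and at 5 kb the class passed (−0.85, adjusted p = 0.0230). Without GFP-targeting counts the own-promoter ratio at 2 kb was −0.12 (20.2% ± 2.94 against 22.0% ± 1.14). The adjusted p by camera was 2.94e-25 for GFP-targeting gRNAs (4.39e-04 with an estimated correlation), 1.61e-06 for the body (0.00636) and 2.65e-04 for intergenic gRNAs (adjusted p = 0.116 with an estimated correlation, and 0.107 with the promoter class at 5 kb). Tiles had adjusted p = 2.82e-12, 4.52e-07, 1.13e-04, 9.53e-04 and 0.0206 in the order given, and 0.0145, 0.0145, 0.0171, 0.105 and 0.434 with an estimated correlation; the tile at 43310000 also ended without GFP-medium replicate 3 (0.0743) or GFP-negative replicate 2 (0.0758). Within replicates 1 and 2 and within replicates 3 and 4 the log2 ratios were 6.28 and 5.61 for GFP-targeting gRNAs, 0.58 and 1.12 for the body, −1.01 (adjusted p = 0.0593) and −1.13 for intergenic gRNAs, −3.73 (adjusted p = 0.288) for the tile at 43311000 in replicates 1 and 2, and −2.32 and −2.38 (adjusted p = 0.123 and 0.0606) for that at 43310000.

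Single gRNAs of this Zfp42 comparison have little support. EdgeR called 49 higher and 294 lower in GFP-negative than in GFP-medium cells, but 0 and 0 with the replicate number as a block, 0 and 0 in replicates 1 and 2 alone, 0 and 0 in replicates 3 and 4 alone, and 2 and 0 when only these 2 populations were fitted. Without GFP-negative replicate 1 it called 0 and 0, the higher number was 31, 9, 13 or 15 without GFP-medium replicate 1, 2, 3 or 4, and the lower number was 189 without GFP-medium replicate 2. DESeq2 called 45 and 252, limma-voom 6 and 18, and the libraries separated completely for 15 (0.383%) and 21 (0.536%) gRNAs, fewer than the 1.43% that exchangeable libraries can give. Of the GFP-targeting gRNAs 7 passed, and 8 adjusted over the list alone, with log2 changes from 5.01 for gRNA 4 (adjusted p = 0.0374) to 8.51 for gRNA 9 (adjusted p = 0.0253). In the 3' part of Zfp42, chr8:43295724-43295746 had 4735 ± 6041 against 29.4 ± 25.4 CPM (log2 6.90, SE 2.52, adjusted p = 0.0422). Upstream, chr8:43310041-43310062 had 3032 ± 3569 CPM in GFP-medium cells and no count in GFP-negative ones, at least 299.7-fold lower (adjusted p = 0.0253). Inside the gene, chr8:43302687-43302708 was at least 204-fold lower (adjusted p = 0.0253), and in the promoter chr8:43308697-43308718 had 10.7 ± 18.8 against 2494 ± 1329 CPM (log2 −8.24, adjusted p = 0.0294).

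Both sorted populations of a line were compared with the same bulk libraries, so their calls are not independent. In the Tdgf1 line 682 gRNAs were depleted in both, where independent lists of 705 and 1278 would share 284; with the replicate number as a block the list of 705 was empty, and the 3 bulk libraries were too few to split, so part of the excess may come from them. For Zfp42 232 were depleted in both, where independent lists of 598 and 265 would share 118. With different bulk libraries for each population, the lists were shorter (505 to 531 and 162 to 183) and shared 153.5 in the median of 6 splits, where independent lists of those lengths would share 66.8 in the median. In both lines such independent lists take every tested gRNA as equally likely to be called. They were not matched on bulk abundance, and splitting the bulk libraries does not change that. The excess therefore cannot tell a shared effect from shared abundance. Simulated unchanged draws give no benchmark for these numbers, since at the dispersion of the libraries the procedure called 0 of 200 simulated gRNAs that had changed 16-fold. No gRNA was called enriched in both by edgeR. In every library of both sorted populations 14 Tdgf1 gRNAs and 1 Zfp42 gRNA lay above every bulk library, fewer than the 46.6 and 7.92 that exchangeable libraries can give.

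In the Nanog line, GFP-targeting and promoter gRNAs took larger shares of GFP-negative than of bulk counts. GFP-targeting gRNAs went from 0.569% ± 0.00738 to 11.1% ± 1.38 (n = 2 each, log2 ratio 4.29) and the 488 own-promoter gRNAs from 9.59% ± 0.413 to 17.8% ± 0.706 (0.89). Singly, edgeR called 0 of 143 tested promoter gRNAs enriched and 5 depleted (0 and 20 at an unadjusted p under 0.05). DESeq2 called 17 and 19 of them, and limma-voom 0 and 20. The gRNAs in the bodies of other genes, Slc2a3 (a glucose transporter) among them, together went from 34.9% ± 2.29 to 13.0% ± 0.811 (−1.42). The rest of the Nanog body (9.92% ± 1.25 in bulk, 13.6% ± 5.12 in GFP-negative) and intergenic gRNAs (45.1% ± 0.622 and 44.5% ± 6.61) did not pass. Camera's adjusted p was 6.14e-11, 0.00251 and 0.00390 for the first 3 classes, but adjusted p = 0.0961, 0.0961 and 0.227 with an estimated correlation. Without GFP-negative replicate 2 the promoter had 0.93 with adjusted p = 0.0698 and bodies of other genes −1.49 with 0.169, and without bulk replicate 1 the latter had −1.35 with 0.0534. The Nanog body passed without bulk replicate 2 (0.59, adjusted p = 0.0404). The median fitted change of the promoter class was 0.01 with TMM (−1.57 with all-zero populations at the floor), 0.94 with DESeq2's size factors, 0.05 with TMMwsp and −1.67 with total counts, so its sign depends on the scaling. An exact permutation test of 2 against 2 cannot go below p = 0.333.

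By position 1 of 39 tiles was higher and 0 were lower, by camera. The tile at chr6:122708000-122708999, just inside Nanog, whose 5' end is at 122707489, held 2.53% ± 0.332 of bulk and 5.33% ± 0.977 of GFP-negative counts (adjusted p = 4.82e-04, 0.646 with an estimated correlation). Without bulk replicate 1 the number of higher tiles was 3, with those at 122707000 (log2 ratio 1.55) and 122715000 (0.88) added. EdgeR called 0 of 1232 gRNAs enriched and 63 depleted (0 and 253 at an unadjusted p under 0.05), and with the replicate number as a block 0 and 0. All 63 had no count in GFP-negative cells. DESeq2 called 57 and 229, limma-voom 6 and 223, and 31 gRNAs (0.791%) lay above and 1094 (27.9%) below in every library, where exchangeable libraries give at most 16.7% each. The enriched number was 133 or 97 without GFP-negative replicate 1 or 2, and the depleted number 0 without either bulk replicate and 369 or 231 without GFP-negative replicate 1 or 2, with the lone library of a population then taken to vary like the other. GFP-targeting gRNAs had log2 changes of 4.83 to 7.17 (edgeR adjusted p from 0.285 to 0.538), and DESeq2 called 9 of the 9 measured. Of gRNAs above bulk in both libraries, chosen after the data were seen, chr6:122703373-122703394, at −4106 bp from the 5' end, had 18681 ± 11793 against 1006 ± 384 CPM (edgeR adjusted p = 0.378, DESeq2 1.52e-04) and chr6:122706716-122706738, at −762 bp, had 3528 ± 642 against 509 ± 70.2 CPM (0.495 and 0.0187). The largest decreases were chr6:122712882-122712903 in the Nanog body (256 ± 23.6 CPM in bulk, at least 14.1-fold lower, adjusted p = 0.0433), chr6:122709622-122709644 (at least 13.6-fold, 0.0437) and chr6:122702683-122702704 (at least 13.7-fold, 0.0415).

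In the Rpp25 line, with 1 library of each population, no test between populations was possible and the values describe these libraries. The title of the GFP-negative library names Rpp26, but its description names the Rpp25 line, and all Rpp25 values rest on that reading. GFP-targeting gRNAs made up 0.815% of bulk counts (exact Clopper-Pearson 95% interval 0.752 to 0.883) and 42.0% of GFP-negative counts (41.8 to 42.1). Own-promoter gRNAs, 666 in number and including all of the short Rpp25 gene, made up 17.1% (16.8 to 17.3) and 46.8% (46.6 to 47.0). Intergenic gRNAs went from 35.5% (35.2 to 35.9) to 7.06% (6.97 to 7.14), bodies of other genes from 34.3% (33.9 to 34.6) to 3.03% (2.97 to 3.09) and ends of other genes from 12.3% (12.1 to 12.6) to 1.14% (1.11 to 1.18). The tile at chr9:57504000-57504999, which holds the Rpp25 5' end at 57504102, went from 4.59% (4.44 to 4.74) to 36.9% (36.8 to 37.1). Such intervals, and the floors behind the lower bounds on folds, cover counting error only, since PCR reads without molecular identifiers are not independent molecules. The median log2 ratio of CPM (with 1 CPM added) was 5.36 for GFP-targeting gRNAs, above all 10000 random sets of the same size matched on bulk abundance. For own-promoter gRNAs the median was −5.37, below 0 although the share rose, and also above all random sets, whose middle value was −7.88; 342 of these gRNAs were detected in bulk and 171 in GFP-negative cells. Of the 10 largest ratios among gRNAs with at least 50 bulk counts, 4 belonged to GFP-targeting gRNAs and 6 to gRNAs in or beside Rpp25. GFP-targeting gRNA 3 led with 51 and 17767 counts (log2 ratio 6.28). The highest positioned gRNAs were chr9:57504341-57504362 (78 and 8070 counts, 4.53), chr9:57504741-57504762 (135 and 10838, 4.16), chr9:57504502-57504523 (55 and 4328, 4.13), and, upstream of the 5' end, chr9:57503898-57503920 (62 and 3719, 3.74).

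**Figure D3:**
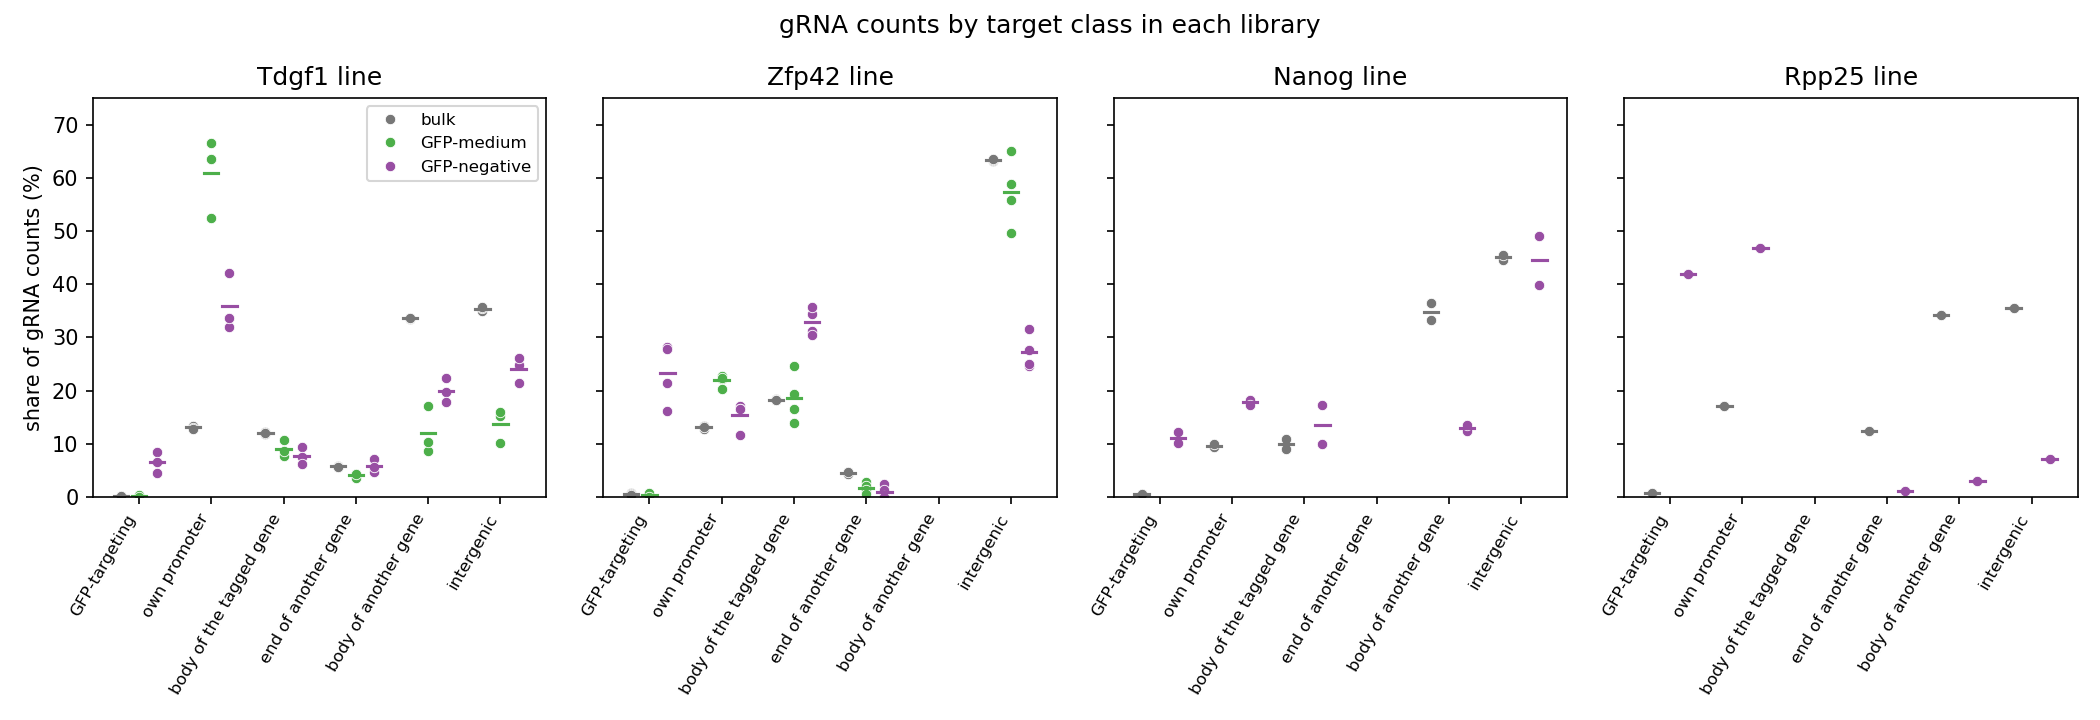
Share of gRNA counts (%) in each library by target class in the 4 lines, with bulk in grey, GFP-medium in green and GFP-negative in purple, a point per library and a line at the mean. GFP-targeting gRNAs reach a mean of 6.52% in Tdgf1, 23.4% in Zfp42 and 11.1% in Nanog and 42.0% in Rpp25 GFP-negative cells, while own-promoter gRNAs reach 60.8% in Tdgf1 GFP-medium cells.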

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

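Of the tests below, that of read depth, those without GFP-targeting counts, and those without the most counted gRNAs of the Zfp42 3' tiles were chosen only after the result was seen, as were the fits within replicates 1 and 2 and within replicates 3 and 4.

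Every GFP-negative library held fewer different gRNAs than any bulk library of its line. Lower read depth is argued against, since the smallest sorted total was at least 1.46 times the largest bulk total in every line (3.06 in Tdgf1, 1.46 in Zfp42, 2.05 in Nanog and 4.49 in Rpp25). If few sorted cells carried each gRNA, presence in different replicates should be close to independent among intergenic gRNAs that had a count in bulk, and in Tdgf1 103 of 1417 were present in every GFP-negative library where independence gives 70.4, a ratio of 1.46 that meets the bound of 1.5 set beforehand but lies above the 58 to 83 found in 2000 shuffles. In Zfp42 12 were present where independence gives 5.35, a ratio of 2.24 outside the shuffled 2 to 10, which argues against independent sampling as the only source. Sparse sampling may still account for part of the missing gRNAs, and unequal abundance or effects of single intergenic gRNAs could also raise the ratio, and no biological explanation was tested.

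The 220 gRNAs of both tiles at the Zfp42 3' end took 19.8% ± 3.48 of GFP-negative and 6.27% ± 0.652 of GFP-medium counts (n = 4 each), with log2 ratios of 1.95 at 43296000 and 1.16 at 43295000, results that stand out because the sorted populations differ from each other. A few dominant gRNAs are argued against, as the log2 ratio for both tiles was 1.66 and still 1.60 without the 3 most counted gRNAs. So is a difference between pairs of replicates, with 1.66 in replicates 1 and 2 and 1.65 in replicates 3 and 4. Sequence composition and matches of these gRNAs elsewhere in the genome were not tested and stay open. No biological explanation was tested.

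Own-promoter gRNAs took a lower share in GFP-negative than in GFP-medium cells, with log2 ratios of −0.76 in Tdgf1 and −0.50 in Zfp42, although camera did not call either. Dilution by GFP-targeting gRNAs is argued against in Tdgf1, where the ratio was −0.66 without their counts (38.5% ± 6.04 against 60.9% ± 7.39). In Zfp42 the ratio without them was −0.12 (20.2% ± 2.94 against 22.0% ± 1.14), so dilution may account for most of the difference there. In Tdgf1 the 3 promoter gRNAs most counted in GFP-medium cells do not account for the difference, with −0.72 without them. A larger group of highly counted gRNAs is not excluded. The median fitted change of the class there was 0.11 with TMM and −0.18 with DESeq2's size factors, so the typical promoter gRNA was not clearly lower. In Zfp42 the ratio without the 3 promoter gRNAs most counted in GFP-medium cells was −0.41, but GFP-targeting counts stayed in its totals. The Zfp42 value therefore cannot tell a few dominant gRNAs from dilution. Sort gates and the number of cells sorted were not given in the sources used here and stay open, and no biological explanation was tested.

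The remaining differences between GFP-negative and GFP-medium cells were log2 ratios of 5.03 for GFP-targeting gRNAs in Tdgf1, and in Zfp42 5.93 for GFP-targeting gRNAs, 0.82 for the Zfp42 body, −1.08 for intergenic gRNAs, and −3.20, −2.98 and −2.35 for the tiles at 43311000, 43321000 and 43310000. With an estimated correlation camera no longer called intergenic gRNAs (adjusted p = 0.116) or the tiles at 43321000 (0.105) and 43310000 (0.434). Zfp42 GFP-negative replicate 2 stood apart from the other 3 in its total of 487732 counts (252023 to 284196 in the others) and in its own-promoter share of 11.7% (16.5% to 17.0% in the others). Chance marks about 1 in 20 groups in this way, and 2 of 27 tests were marked.

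Other splits of the libraries tested whether chance could give as many gRNAs past edgeR's test. In Zfp42 1 of 35 splits gave as many as the real one for GFP-negative against bulk (606 gRNAs, highest other split 0) and 1 of 35 for GFP-medium against bulk (265, highest other 0). Since the numbers pair the samples, the real split is to be set beside the 8 splits, itself included, that part every pair; among the others of these the highest was 0 in both, and 8 splits are too few for a share under 0.05. For GFP-negative against GFP-medium 3 of 35 splits gave as many as the real 343, the highest of the others 355, so chance cannot be excluded. Other splits gave 225.5 gRNAs in the median and the split into replicates 1 and 2 against 3 and 4 gave 270. The bulk libraries stayed in all these fits. With only the 2 sorted populations in the fit the real split gave 2 enriched and 0 depleted. Why mixed splits gave so many gRNAs was not tested. Among the 8 splits that part every pair, the highest other than the real one was 194; with the replicate block the real split gave 0 enriched and 0 depleted. In Tdgf1 the 10 splits are too few for a share under 0.05: 1 of 10 was as large for GFP-negative against bulk (705, highest other 0), 1 of 10 for GFP-medium against bulk (1278, highest other 0) and 10 of 10 for GFP-negative against GFP-medium (0, highest other 0).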

How the results depend on the processing

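Counts of gRNAs whose libraries separate completely, fits within replicates 1 and 2 and within replicates 3 and 4 of Zfp42, classes without their 3 most counted gRNAs and shares without GFP-targeting counts were chosen only after the results were seen. Over 191 results for classes and named gRNAs 3035 of 3547 alternative values kept their side of the threshold, 255 lost a call and 251 gained one. A further 6 turned direction with a call before or after. Over 35 tiles 400 of 435 kept their side, 28 lost a call, 5 gained one and 2 turned with a call before or after. A turn of direction between values that both missed the threshold was counted as kept. Of 230 alternative counts of tiles 200 stayed within 1.5 times. By the same measure counts of enriched and depleted gRNAs stayed in 23 of 38 alternatives for Tdgf1 GFP-negative against bulk, 21 of 38 for GFP-medium against bulk and 33 of 38 between the sorted populations, in 32, 31 and 29 of 48 for Zfp42, and in 9 of 26 for Nanog, and those of gRNAs moved in both sorted populations in 5 of 10. Rpp25 medians stayed within their intervals in 7 of 20. In simulated counts of these depths all 100 gRNAs raised 16-fold were called at a dispersion of 0.1 and 0 of 100 at that of the libraries. Within the simulation the spread between replicates thus limited calls of single gRNAs. It drew bulk and sorted libraries with the same dispersion, although real bulk replicates lay closer together, so power in the real comparisons was not measured. Depth sets how low a missing gRNA can be placed (3 counts are 4.17 to 76.7 CPM). Where a value below differs from that of the edgeR test with TMM, the cause was not tested, except that fewer libraries, gRNAs or replicates enter where the setting says so, and without a GFP-negative or bulk replicate of Nanog the lone library was taken to vary like the other population.

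In Tdgf1 GFP-negative against bulk, with 0 gRNAs enriched and 705 depleted, DESeq2 called 40 enriched, limma-voom 22 enriched and 1739 depleted, a fit of only the 2 populations 9 enriched, and 59 above and 1646 below separated completely. In Tdgf1 GFP-medium against bulk, with 0 and 1278, enriched counts were 2 with DESeq2's size factors, 2 with TMMwsp, 83 with DESeq2, 24 with limma-voom, 9 with only the 2 populations and 29 by separation, and depleted counts 2176 with limma-voom and 2284 by separation. In Tdgf1 GFP-negative against GFP-medium, with 0 and 0, DESeq2 called 300 and 44, limma-voom 8 enriched, and 83 and 11 separated. Of gRNAs moved in both sorted populations 14 were above and 1434 below bulk by separation.

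In Zfp42 GFP-negative against bulk, with 8 and 598, enriched counts were 14 with TMMwsp, 58 with DESeq2, 19 with limma-voom, 18 with only the 2 populations, 0 in replicates 1 and 2, 5 in replicates 3 and 4 and 16 by separation, and depleted counts 944 without a filter and 1017 with limma-voom. In Zfp42 GFP-medium against bulk, with 0 and 265, enriched counts were 2 with DESeq2's size factors, 3 with TMMwsp, 33 with DESeq2, 9 with limma-voom, 2 with only the 2 populations and 10 by separation, and depleted counts 564 without a filter, 663 with limma-voom, 0 in replicates 3 and 4 and 689 by separation. In Zfp42 GFP-negative against GFP-medium, with 49 and 294, limma-voom called 6 and 18, the fit of only these populations 2 and 0, replicates 1 and 2 alone 0 and 0, replicates 3 and 4 alone 0 and 0, and 15 and 21 separated. Of gRNAs moved in both sorted populations 1 was above and 548 below by separation, and with split bulk libraries 153.5 were depleted in the median.

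In Nanog GFP-negative against bulk, with 0 and 63, enriched counts were 57 with DESeq2, 6 with limma-voom and 31 by separation, and depleted counts 99 with TMMwsp, 217 with total counts, 0 without a filter, 0 with a bulk mean of at least 10, 229 with DESeq2, 223 with limma-voom and 1094 by separation. With an estimated correlation the log2 ratios of 4.29 for GFP-targeting and 0.89 for own-promoter gRNAs had adjusted p = 0.0961. In Rpp25 the GFP-targeting median was 6.79 after scaling, and the own-promoter median was −2.95 with 10 CPM added, −7.51 with 0.1 CPM and −2.45 among gRNAs with at least 50 bulk counts.

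Among classes, the Zfp42 promoter at 5 kb turned to −0.19 in GFP-negative against bulk (adjusted p = 0.00648) and passed at −0.85 in GFP-negative against GFP-medium (adjusted p = 0.0230). The Zfp42 body in GFP-medium against bulk turned to −0.26 in replicates 3 and 4 (adjusted p = 0.0653) and to −0.23 without its 3 most counted gRNAs (adjusted p = 0.00648), and the tile at 43294000 in GFP-negative against bulk to −0.00475 in replicates 3 and 4 (adjusted p = 0.0537). The number of higher tiles in Tdgf1 was 3 with 2-kb tiles (GFP-negative) and 8 with 500-bp tiles (GFP-medium), and 2 with 500-bp tiles in Nanog. With an estimated correlation it was 0 for both Tdgf1 comparisons with bulk, 2 for Zfp42 GFP-negative, 0 for Zfp42 GFP-medium and 0 for Nanog.

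With the replicate number as a block the depleted count of Tdgf1 GFP-negative against bulk was 0, both counts of Zfp42 GFP-negative against GFP-medium were 0 and 0, and that of Nanog was 0. The block changed no other count of gRNAs and no count of higher tiles by 1.5 times or more, and no call of a class; the lower tiles of Tdgf1 GFP-medium against bulk fell to 3, and some named gRNAs lost their call, GFP-targeting gRNAs 6 and 8 of Zfp42 GFP-negative against bulk among them. In Nanog the residuals of same-numbered libraries correlate at 0.425 and those of the others at −0.425, but with 2 replicates these are mirror values by construction, so whether the numbers pair samples there cannot be told.

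Leaving out each library in turn gave 0 to 5 enriched and 462 to 1341 depleted gRNAs in Tdgf1 GFP-negative against bulk, 0 to 6 and 0 to 1761 in Tdgf1 GFP-medium against bulk, 3 to 13 enriched in Zfp42 GFP-negative against bulk, 0 to 2 and 257 to 482 in Zfp42 GFP-medium against bulk, 0 to 55 and 0 to 318 in Zfp42 GFP-negative against GFP-medium, and 0 to 133 and 0 to 369 in Nanog. Log2 ratios ranged from −0.17 to 0.13 for gRNAs at the end of Lrrc2 in Tdgf1 GFP-negative against bulk (lowest without GFP-negative replicate 1), from −1.12 to 0.42 for GFP-targeting gRNAs in Tdgf1 GFP-medium against bulk, from −0.14 to 0.14 for the Zfp42 body in GFP-medium against bulk, from −0.0172 to 0.16 for the tile at 43294000 and from 0.85 to 0.94 for the Nanog promoter. The number of higher tiles ranged from 3 to 6 in Tdgf1 GFP-negative against bulk and from 1 to 3 in Nanog.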

Other observations

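The test within pairs and the cluster of gRNAs below were chosen after the values were seen, the counts within replicates 1 and 2 and within replicates 3 and 4 and without the 3 most counted gRNAs were chosen after seeing the data, and all other values here are descriptions without a test unless a test is named.

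Upstream of Zfp42, 442 gRNAs formed a cluster at chr8:43320176-43324022, 13.2 to 17.0 kb from the annotated 5' end, in intergenic sequence. Together they took 9.62% to 11.1% of bulk counts, 17.2% to 33.1% of GFP-medium counts and 3.53% to 6.97% of GFP-negative counts, so their share was higher than bulk in every GFP-medium library and lower than bulk in every GFP-negative library (n = 4 each). The log2 ratio of GFP-medium to bulk was 1.09, with 0.79 in replicates 1 and 2, 1.33 in replicates 3 and 4, and 0.80 without the 3 most counted gRNAs. GFP-negative cells lay at −2.28 against GFP-medium cells (−2.30 and −2.26 within the pairs of replicates). Exact permutation tests of the shares gave p = 0.0286 for each sorted population against bulk, the smallest possible (adjusted p = 0.0308 over 14 tests of 7 clusters), and 0.125 when only same-numbered libraries were swapped, the smallest that 4 pairs allow, which leaves that test without a say. By camera the cluster did not stand out from the other gRNAs in GFP-medium cells (adjusted p = 0.355), it was lower in GFP-negative than in bulk (adjusted p = 0.0148, 0.228 with an estimated correlation) and lower than in GFP-medium (adjusted p = 5.75e-04, not called with an estimated correlation). Single gRNAs differed widely: chr8:43320710-43320732 had 14947 ± 11314 CPM in GFP-medium and 653 ± 91.8 in bulk, chr8:43320826-43320847 had 5954 ± 2273 and 733 ± 119, and chr8:43320967-43320988 had 14610 ± 12016 and 1586 ± 592 (edgeR adjusted p = 0.0737, 0.290 and 0.223). In GFP-negative cells the former 2 had 1548 ± 1209 and 2748 ± 3537 CPM, means above bulk unlike the cluster as a whole. Both start 1 bp below the Zfp42 sites listed for deep sequencing, which the sample titles name Zfp42 Enhancer. The tiles at 43320000 and 43321000 held 7.16% ± 1.42 and 8.30% ± 3.18 of GFP-medium counts against 2.57% and 2.98% of bulk, and neither passed (adjusted p = 0.941 and 0.154).

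The clusters of gRNAs farther upstream of Zfp42 were lower in both sorted populations. Those at chr8:43328013-43334012 took 15.7% of bulk, 6.51% of GFP-medium and 4.92% of GFP-negative counts, and those at chr8:43352010-43355980 took 2.83% of GFP-medium and 1.58% of GFP-negative counts, log2 ratios to bulk of −1.50 and −2.34 (camera adjusted p for GFP-negative against bulk 2.72e-04 and 4.30e-06, or 0.0937 and 0.0561 with an estimated correlation). In the Nanog line gRNAs at Slc2a3, which codes for a glucose transporter, went from 28.8% to 10.5% (adjusted p = 0.0248, 0.328 with an estimated correlation), and the cluster around Nanog from 38.1% to 60.3% (adjusted p = 2.79e-04, 0.136 with an estimated correlation). In the single Rpp25 libraries gRNAs at Scamp5, which codes for a secretory carrier membrane protein, took 21.1% of bulk and 2.88% of GFP-negative counts, and the cluster around Rpp25 42.0% and 53.0%. At Cox5a, a subunit of cytochrome c oxidase, 1 cluster took 16.2% and 1.00% and another 5.37% and 0.0815%.

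All 6 sites listed for deep sequencing match a gRNA that starts 1 bp lower, 1 of them also a gRNA at the listed start, and which gRNA is meant is not given in the sources used here. In the Tdgf1 line chr9:110947444-110947466 had 465 ± 205 CPM in bulk, 8484 ± 4949 in GFP-medium and 5050 ± 5237 in GFP-negative cells (n = 3), while the gRNA at the listed start, chr9:110947445-110947467, had 14.8 ± 13.99, 6.16 ± 10.7 and 77.4 ± 134 with counts in 1 of 3 libraries of each sorted population. Of the gRNAs 1 bp below the other listed starts, chr9:110947456-110947477 had 81.4 ± 125, 28.1 ± 48.8 and 45.6 ± 79.0. The intergenic chr9:110934425-110934447 had 433 ± 75.6 CPM in bulk, no count in GFP-medium and 2581 ± 4322 in GFP-negative cells, with counts in 2 of 3 libraries, and chr9:110934269-110934291 had 191 ± 125, 149 ± 259 and 61.6 ± 107. Values of the gRNAs 1 bp below the Zfp42 sites are given above with the upstream cluster.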
